A study of Mus musculus with 2 samples.

How the data were processed

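ATAC-seq libraries were made by Nextera tagmentation with a fragment size range of 200 to 750 bp, per the labels, from 2 pools of mouse hindbrain at embryonic day 12.5. The groups and replicate numbers were taken from the labels, which state 2 biological replicates of 120 and 88 embryos. The deposited peak lists were derived from the authors' filtered alignments on mm10, per the file headers. The aligner, the peak caller and their versions are not given in the sources used here. The shift of reads for the transposase offset is likewise not given in the sources used here.

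The deposited lists are in narrowPeak format, per the file headers. Their signal column is a fold enrichment, a linear ratio that the authors' caller computed from the pileup over the local background, (pileup + 1)/(background + 1) as judged from the low values. A second column holds the −log10 p of the authors' caller for each peak, and the deposited ranked tables hold the −log10 of the irreproducible discovery rate (IDR), a measure of how consistently a peak ranks in a pair of lists. For each replicate there was a ranked list, a thresholded list and a larger overlap list, called on that library alone. For both libraries pooled there were a conservative list, an optimal list and a replicated list. Every one of the 76635 peaks of the conservative list was found in the first pooled ranked table, where 77006 peaks passed an IDR of 0.05, so that 371 had been removed by a further filter of the authors. The steps of the fold values implied the background pileup of each library, 6.16 and 6.22 reads, and 12.4 in the pooled table, equal to the sum of the replicates. The files hold no read totals, so precision was judged from the spread of the replicates and, for shares, from 95% Wilson intervals.

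Overlapping peaks of a list were merged into regions, since the caller wrote several summits per region. The conservative list was the main set. The columns of replicate values in its ranked table carry no names, so each replicate's fold for a region was taken from that replicate's own ranked list, as the highest fold among peaks whose summit lay inside the region. The summit condition was set after the data had been seen, because peaks that overlapped a region with a summit outside it gave false ratios. The version with any overlapping peak was kept as an added alternative. Values were missing for 358 regions in replicate 1 and 312 in replicate 2.

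The reference was the same assembly with the GENCODE M21 annotation. Only protein-coding genes were used, 21853 with 54361 TSSs. Regions within 1 kb of a TSS were called promoter, others were assigned to coding exon, untranslated exon, intron or intergenic sequence by their summit. Distal regions were given to the nearest coding TSS within 100 kb. A gene's territory ran to the midpoint to its neighbours and at most 100 kb on each side. The 22 gene lists and 24 motifs were written from textbook knowledge. Symbols of 2 listed genes, Drgx and Ahsp, were not matched, and a few genes stood in more than 1 list. All tests were two-sided at an adjusted threshold of 0.05 with Benjamini-Hochberg adjustment over the lists or motifs. Promoter lists and motifs were tested with Fisher's exact test, distal lists and CpG-matched lists with 10000 random lists drawn within 10 deciles of territory length or of CpG within 500 bp of the TSS, and Hox genes with 100000 permutations over genes. Overlap by chance came from 100 circular shifts. Copies and mitochondrial-like stretches were searched with blastn 2.17.0 in stretches of at least 100 bp, at 90% and 80% identity.

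Genes and regions were named by a rule, namely up to 3 members of each list with the highest promoter fold and up to 3 without a promoter region in list order, Hox genes of groups 1, 2, 4, 9 and 13, the 15 genes with the most distal regions, the 10 strongest distal regions, and the 5 largest replicate ratios in each direction above the median fold. Sox9, Sox1, Dll1, Ascl1, Hes1, Epha4, Meis1, Meis2 and Mab21l1 were named outside it, chosen after their values were seen. The samples, tests, lists, motifs, naming rule and most alternatives were fixed before the data were examined.

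Alternatives covered the overlap rule, the list used, the distance to a TSS, the −log10 p in place of the fold, CpG matching, permuted motifs and leaving out each replicate. Most procedures were tested on simulated data, but not the CpG matching, the permuted motifs or the searches for copies and mitochondrial-like stretches. Lists simulated at 95% or 10% open among 21853 genes were called in 100% of cases and unchanged lists in 0%. For distal regions, lists at 4 times the rate were called in 60% of cases by the median and in 100% by the mean, and unchanged lists in 0% and 5%. Implanted motifs in 3000 regions were called in 100% of cases and simulated Hox gradients over 39 genes in 100%. Simulated summits and flanks had the same base composition, so the effect of a difference in G and C was not simulated. The pooled pseudoreplicated overlap list was not used here. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9.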

Results

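Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into exposed DNA, in the hindbrain of mouse embryos of strain B6NCrl at embryonic day 12.5. At this stage the hindbrain holds dividing progenitors along the ventricle, newly born neurons of the brainstem and the early cerebellum. The data comprised 1 group of 2 biological replicates, a pool of hindbrains from 120 embryos (replicate 1) and a pool from 88 embryos (replicate 2), both of mixed sex. No second tissue, stage or treatment was part of the series. The comparisons therefore set the replicates against each other, and gene groups, region classes and sequence motifs against a background within the same tissue. All positions are on mm10.

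The authors' list of regions reproducible between the replicates, called the conservative list below, held 25785 accessible regions covering 27.4 Mb, with a median width of 1054 bp. A region's fold is the authors' own enrichment of the read pileup over the local background. Its median over the conservative list was 6.03 and its maximum 53.8. Total read counts were not used here, so the depth of the libraries is unknown. The background pileup implied by the fold values was 6.16 reads in replicate 1 and 6.22 in replicate 2, an inference from the steps of their low values, since the formula is not given in the sources used here.

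Both pools of embryos gave largely the same map. Replicate 1 had 18722 regions in its own thresholded list and replicate 2 had 18900, a mean of 18811 ± 126 (SD, n = 2). Of replicate 1's regions, 16072 (85.8%) overlapped a region of replicate 2 by at least 1 bp, and 16030 (84.8%) of replicate 2's regions overlapped one of replicate 1. The same regions shifted along their chromosomes overlapped in 1.54% and 1.53% of cases on average. Regions not shared were weaker, with a median fold of 5.06 in replicate 1 and 5.13 in replicate 2, against 7.57 and 7.5 for shared regions. Most of them were nevertheless ranked in the other replicate, 94.0% of those of either replicate. The share called common depended on the rule and fell to 74.5% when the strongest summits had to lie within 100 bp.

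Fold values were close between the pools region by region. Across 25198 conservative regions with a value in each replicate, Pearson's r of log2 fold was 0.932 and Spearman's rho was 0.920. This is a correlation across regions, which are not independent replicates. The SD of a single replicate was 0.15 on the log2 scale, or 1.11-fold. The conservative list was selected for agreement between these replicates, so few discordant regions can be left in it. After centring, 2 of the 25198 regions (0.00794%) differed more than 2-fold, against 65 of the 35385 (0.184%) with a value in each replicate among all 62207 ranked regions. One lay in intergenic sequence at chromosome 4, 69255916 to 69256853, 301975 bp from the promoter of Brinp1, a neural regulator of cell proliferation. Its fold was 3.91 in replicate 1 and 8.0 in replicate 2. The other was the promoter of Ttc25, a gene of motile cilia, at chromosome 11, 100545019 to 100545937, where the fold was 11.3 in replicate 1 and 5.54 in replicate 2. Among regions above the median fold, the next largest ratios in favour of replicate 2 lay nearest to Hmces, Brinp3, Gdf6 and Basp1, with centred log2 ratios from 0.92 down to 0.82. Those in favour of replicate 1 lay nearest to Rec114, Zfp612, Lamp5 and Gm21887, with ratios from -0.97 to -0.85. With 1 library per replicate none of these was tested. The share of regions beyond the cutoff was 1.92% when the caller's −log10 p took the place of the fold and 1.21% at a cutoff of 1.5-fold.

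Promoters made up nearly as many of the accessible regions as distal sequence and were the stronger class. Of the conservative regions, 12484 (48.4%, 95% Wilson interval 47.8 to 49.0%) lay within 1 kb of a transcription start site (TSS) of a protein-coding transcript. Introns held 5486 regions (21.3%), intergenic sequence 7373 (28.6%), coding exons 240 (0.931%) and untranslated exons 202 (0.783%). The median fold of promoters was 7.80 in replicate 1 and 7.74 in replicate 2, against 4.93 and 4.92 for distal regions. The difference of medians was 0.66 ± 0.008 on the log2 scale (SD, n = 2), many times the spread between the replicates. The 13301 distal regions lay a median of 42.7 kb from the nearest coding TSS, and 9590 (72.1%) lay within 100 kb of one. The promoter share was 59.4% in replicate 1's own list and 59.2% in replicate 2's, and 26.2% in the authors' larger replicated list of 60556 regions. These intervals cover counting error only.

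In the conservative list, hindbrain patterning, neural progenitor, postmitotic neuron and housekeeping genes had open promoters more often than other genes. The call for hindbrain patterning was lost in the optimal list, the replicated list and both replicates' own lists, and that for neurons in replicate 1's own list. The lists of rhombic lip genes and brainstem neuron types did not pass. Genes of muscle, liver, microglia, chemoreceptors and posterior Hox groups were open less often. A promoter was called open when a conservative region lay within 1 kb of any TSS of the gene, which held for 12639 (57.8%) of 21853 protein-coding genes. Of 22 gene lists, 11 differed from the other genes by Fisher's exact test after Benjamini-Hochberg adjustment, 4 with more open promoters and 7 with fewer. Genes are not replicates, and neighbouring genes of a family are not independent, so these tests describe the present libraries.

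Of the hindbrain patterning genes, 17 of 20 were open (85%, adjusted p = 0.0255, Fisher's exact test). The strongest was Pbx1, a homeodomain cofactor of Hox proteins, with a fold of 12.6 ± 0.262 (SD, n = 2) at chromosome 1, 168431658 to 168432918. Pax5, which acts at the midbrain-hindbrain boundary, followed at 11.2 ± 0.879 (chromosome 4, 44704085 to 44704915), and Pbx3 at 8.56 ± 0.277. Fgf8 and Wnt1, the signals of the isthmic organizer, and Cyp26c1, a retinoic acid hydroxylase, had no conservative promoter region. The neural progenitor list also had 17 of 20 promoters open (adjusted p = 0.0255, Fisher's exact test). Its highest folds were at Fabp7, the radial glial fatty acid binding protein (7.45 ± 0.0917), Vim, an intermediate filament of neuroepithelial cells (7.11 ± 0.135), and Hes6, a bHLH factor of neurogenesis (7.01 ± 0.0887). The receptors Notch1 and Fgfr3 and the RNA-binding Msi1 were not open in the conservative list but were open in replicate 1's own list, where all 20 genes were. Postmitotic neuron genes were open in 17 of 20 cases as well (adjusted p = 0.0255, Fisher's exact test). They were led by Syt1, the calcium sensor of synaptic vesicles (14 ± 0.381, chromosome 10, 109010254 to 109011937), the neuronal RNA-binding Elavl4 (9.98 ± 1.06) and the microtubule protein Map2 (9.74 ± 1.48). Slc17a6 and Slc32a1, the vesicular transporters of glutamate and of GABA and glycine, and the bHLH gene Nhlh2 had no conservative promoter region. In the authors' replicated list all 20 neuron genes were open (adjusted p = 0.000781, Fisher's exact test). In the conservative list, the region of 1 of the 17 open neuron genes also lay within 1 kb of a TSS of another gene. The list was not tested without it.

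Housekeeping genes were open in 20 of 20 cases (adjusted p = 0.00013, Fisher's exact test), with Eef1a1 at a fold of 13.4, Sdha at 11.7 and Rplp0 at 11.2. The Sdha region also lay within 1 kb of a TSS of Ccdc127. The median fold of open promoters was 9.24 in the housekeeping list, against 5.44 for hindbrain patterning, 5.31 for progenitors and 6.06 for neurons. The call for hindbrain patterning rested on the list of regions used: 16 of 20 promoters were open in the optimal list (adjusted p = 0.124), 17 of 20 in the replicated list (adjusted p = 0.0974) and 14 of 20 in each replicate's own list (adjusted p = 0.230 and 0.245, all by Fisher's exact test), so none of these passed. Among regions above the median fold the difference from other genes was -9.53 percentage points. That subset also turned the progenitor difference to -19.5 points and ended the call for neurons (adjusted p = 0.412, Fisher's exact test). The neuron list had 15 open promoters in replicate 1's own list (adjusted p = 0.0969, Fisher's exact test) and 16 in replicate 2's (adjusted p = 0.0498).

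Of these lists, only that of neuron genes passed after matching on CpG content, and the lists were not tested against each other. Against random lists matched on the observed over expected CpG of the promoters, neuron genes remained more often open (85% against 66.6%, adjusted permutation p = 0.0376). Hindbrain patterning genes (85% against 84.7%) and progenitor genes (85% against 84.0%) were open as often as matched genes, with an adjusted permutation p of 1 for either list. The test could not have called the hindbrain patterning list, since 20 of 20 open promoters would have given an adjusted permutation p of 0.0717. Housekeeping genes were open in 100% against 88.9% of matched genes (adjusted permutation p = 0.323), the highest share possible, so this test could not have called them either.

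The remaining lists of neural identities, within the hindbrain and outside it, did not pass the test against all genes in the conservative list. Rhombic lip and cerebellar genes were open in 15 of 20 cases (adjusted p = 0.272, Fisher's exact test), with Rora, the orphan receptor of Purkinje cells, at a fold of 7.5, Lhx1 at 6.5 and Pax6, a regulator of granule cell precursors, at 6.45, and no region at Barhl1, Lmx1a or Olig3. Among regions above the median fold the difference of this list turned to -29.5 percentage points (adjusted p = 0.0206, Fisher's exact test), and in the replicated list 20 of 20 were open (100% against 64.4%, adjusted p = 0.000781, Fisher's exact test). Brainstem neuron type genes were open in 8 of 20 cases (adjusted p = 0.198, Fisher's exact test). Tbx3 had a fold of 9.36, Isl2, a motor neuron LIM gene, 8.58 and Gata3, a gene of V2b and serotonergic neurons, 8.0. The noradrenergic and visceral motor gene Phox2a, the motor neuron gene Mnx1 and the serotonergic gene Fev had none. In the replicated list the brainstem share was 25.6 percentage points above other genes (adjusted p = 0.0298, Fisher's exact test), while matching on CpG gave 40% against 74.0% (adjusted permutation p = 0.00176). Oligodendrocyte lineage genes were open in 4 of 10 cases (adjusted p = 0.467, Fisher's exact test), among them Pdgfra (6.36), Olig1 (6.07) and Olig2 (4.58) but not Sox10, Nkx2-2 or Cspg4. Choroid plexus and roof plate genes were open in 3 of 10 (adjusted p = 0.197, Fisher's exact test), namely Bmp6 (6.72), Msx2 (6.25) and Msx1 (4.34), with none at the choroid plexus genes Ttr, Folr1 and Clic6. Forebrain regulators were open in 10 of 20 (adjusted p = 0.583, Fisher's exact test), including the interneuron genes Dlx1 (7.43), Lhx8 (6.70) and Arx (6.57) but not Emx2, Dlx5 or Lhx6. Against CpG-matched genes this share was lower (50% against 88.4%, adjusted permutation p = 0.0011).

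Promoters of microglia, liver, muscle and chemoreceptor genes were largely closed in the conservative list. There, lists of endothelium, mesenchyme, neural crest, blood and limb did not pass the test. Of the microglia and macrophage genes 1 of 15 was open (adjusted p = 0.00016, Fisher's exact test), Irf8 at a fold of 5.73, while Csf1r, Cx3cr1 and Aif1 had no conservative region. Of the hepatocyte genes 1 of 15 was open (adjusted p = 0.00016, Fisher's exact test), the apolipoprotein gene Apoa1 at 7.68, and Alb, Afp and Apoa2 had none. All 15 cardiac and skeletal muscle genes lacked a conservative region (adjusted p = 1.72e-05, Fisher's exact test), the myosins Myh6 and Myh7 and the cardiac factor Nkx2-5 among them. Among CpG-matched genes the muscle list was still lower (0% against 31.7%, adjusted permutation p = 0.0044), whereas microglia (6.67% against 15.2%, adjusted permutation p = 0.601) and hepatocyte genes (6.67% against 17.6%, adjusted permutation p = 0.575) did not pass. With none of their promoters open, these 2 would have had an adjusted permutation p of 0.0845 and 0.161, so this test could not have called them. In the replicated list 5 of 15 muscle genes were open, Myh7 among them (adjusted p = 0.0284, Fisher's exact test). Microglia genes, with Csf1r, and hepatocyte genes had 3 of 15 open there (adjusted p = 0.00157 for each, Fisher's exact test). These lists still stayed below other genes. Endothelial genes were open in 7 of 15 cases (adjusted p = 0.535, Fisher's exact test), with Ets1 at 10.6, Erg at 8.22 and the VEGF receptor Kdr at 5.95, and none at Cdh5, Pecam1 or Tek. Mesenchyme, meninges and pericyte genes were also open in 7 of 15 (adjusted p = 0.535, Fisher's exact test), led by Foxc1 (5.53), Tbx18 (5.29) and Foxd1 (4.98), with none at Col3a1, Foxc2 or Twist2. In replicate 1's own list these 2 lists had 3 of 15 promoters open each and fell below other genes (adjusted p = 0.0308, Fisher's exact test), and in replicate 2's 4 of 15 (adjusted p = 0.104, Fisher's exact test). Neural crest and cranial ganglion genes were open in 7 of 11 (adjusted p = 0.770, Fisher's exact test). Their strongest regions were at Mpz (10.6), which also lay within 1 kb of a TSS of Sdhc, at Eya1 (8.17) and at Isl1 (7.56), and Sox10, Foxd3 and Ntrk1 had none. Erythroid genes were open in 4 of 11 cases (adjusted p = 0.324, Fisher's exact test), with Klf1 at 5.38, Tal1 at 4.75 and Gypa at 4.14 but nothing at Gata1 or the globin genes Hba-a1 and Hbb-bt. Limb patterning genes were open in 6 of 12 (adjusted p = 0.603, Fisher's exact test), with Grem1 at 5.24, Fgf10 at 4.58 and Lhx2 at 4.47, and not at Tbx4, Tbx5 or Pitx1, and their share was below that of CpG-matched genes (50% against 82.1%, adjusted permutation p = 0.028). Above the median fold no mesenchyme (adjusted p = 0.000915), erythroid (adjusted p = 0.00407) or limb gene (adjusted p = 0.00286, all by Fisher's exact test) was open and these lists fell below other genes, and in the replicated list 11 of 11 neural crest genes were open (adjusted p = 0.0205, Fisher's exact test). Olfactory receptor promoters were open in 2 of 1133 cases, Olfr658 (7.79) and Olfr94 (6.68), and vomeronasal receptors in 1 of 328 (adjusted p = 1.6e-121, Fisher's exact test). The latter, Vmn1r4 (11.4), shared its region with Nt5c3. Against CpG-matched genes both receptor lists remained lower by a small margin, 0.177% against 4.23% (adjusted permutation p = 0.0011) and 0.305% against 2.16% (adjusted permutation p = 0.0132).

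**Figure D1:**
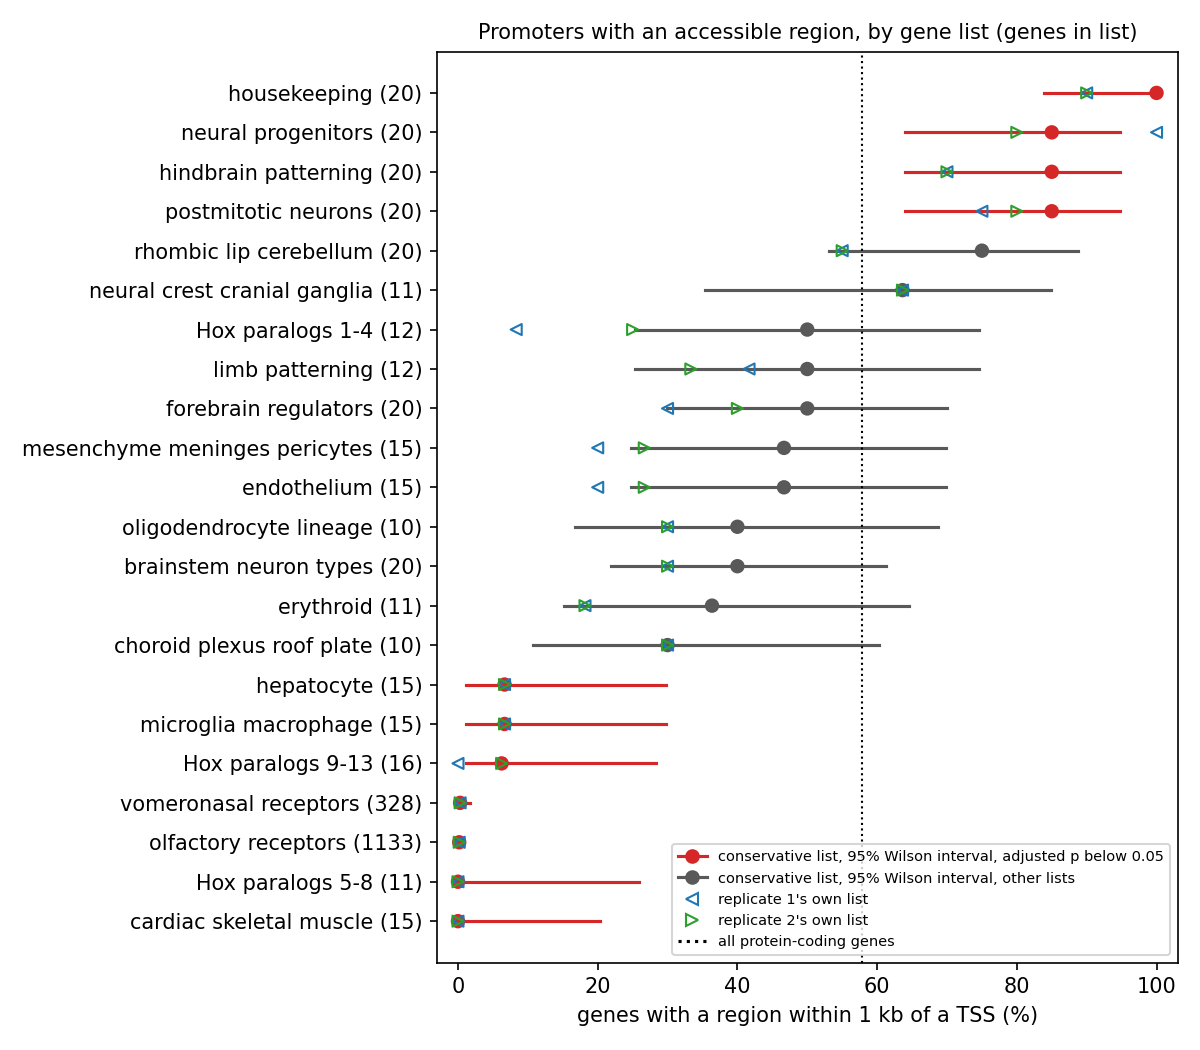
Share of genes with an accessible region within 1 kb of a TSS (x axis, percent) for each of the 22 gene lists (y axis, number of genes in parentheses), with filled points and 95% Wilson intervals for the conservative list and triangles for each replicate's own list. The 4 lists with more open promoters sit at 85% or above, right of the 57.8% of all protein-coding genes, and the 7 with fewer sit at 6.67% or below.

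Among the 22 lists, neural progenitor genes had the most distal accessible regions per gene. Each distal region within 100 kb of a coding TSS was given to the nearest gene, and each list was set against 10000 random lists matched on the length of the genes' territories. The neural progenitor list had a median of 2.5 distal regions per gene, against 0.0705 on average in random lists (raw p = 0.0002, the smallest that 10000 permutation lists can give, adjusted p = 0.0044), and 18 of its 20 genes had at least 1. Sox9, a glial and progenitor factor, had 7 such regions, and Sox1, Notch1, Dll1, Ascl1 and Hes1 had 5 each. In each replicate's own list Sox9 had 5 and 4, and the other 5 genes had 2 to 4. The median was 2 in postmitotic neurons against 0.155 (adjusted permutation p = 0.0066) and 1.5 in both hindbrain patterning and rhombic lip genes, against 0.282 and 0.276 (adjusted permutation p = 0.0484 for each). Among patterning genes Epha4, an ephrin receptor, had 7 (3 and 2 in the replicates' own lists), and Meis1 and Meis2, cofactors of Hox proteins, had 5 each (3 and 4, and 3 and 2). In the rhombic lip list Mab21l1 had 6 and Pax6 had 5 (4 and 3 for both). In each replicate's own list the progenitor median was 2 (adjusted permutation p = 0.0044 in both), while the other 3 lists no longer passed (adjusted permutation p from 0.152 to 0.266). Hindbrain patterning (adjusted permutation p = 0.261) and rhombic lip genes (adjusted permutation p = 0.209) did not pass within 50 kb, nor rhombic lip genes in the optimal list (adjusted permutation p = 0.0528). Among regions above the median fold the hindbrain patterning list alone passed, and the progenitor list did not (adjusted permutation p = 1). None of the other 18 lists passed with the median, whose random value was near 0 for many lists. With the mean in its place, olfactory receptors (0.0291 regions per gene) and vomeronasal receptors (0.0457) also had fewer than matched lists (adjusted permutation p = 0.00147 for either).

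**Figure D2:**
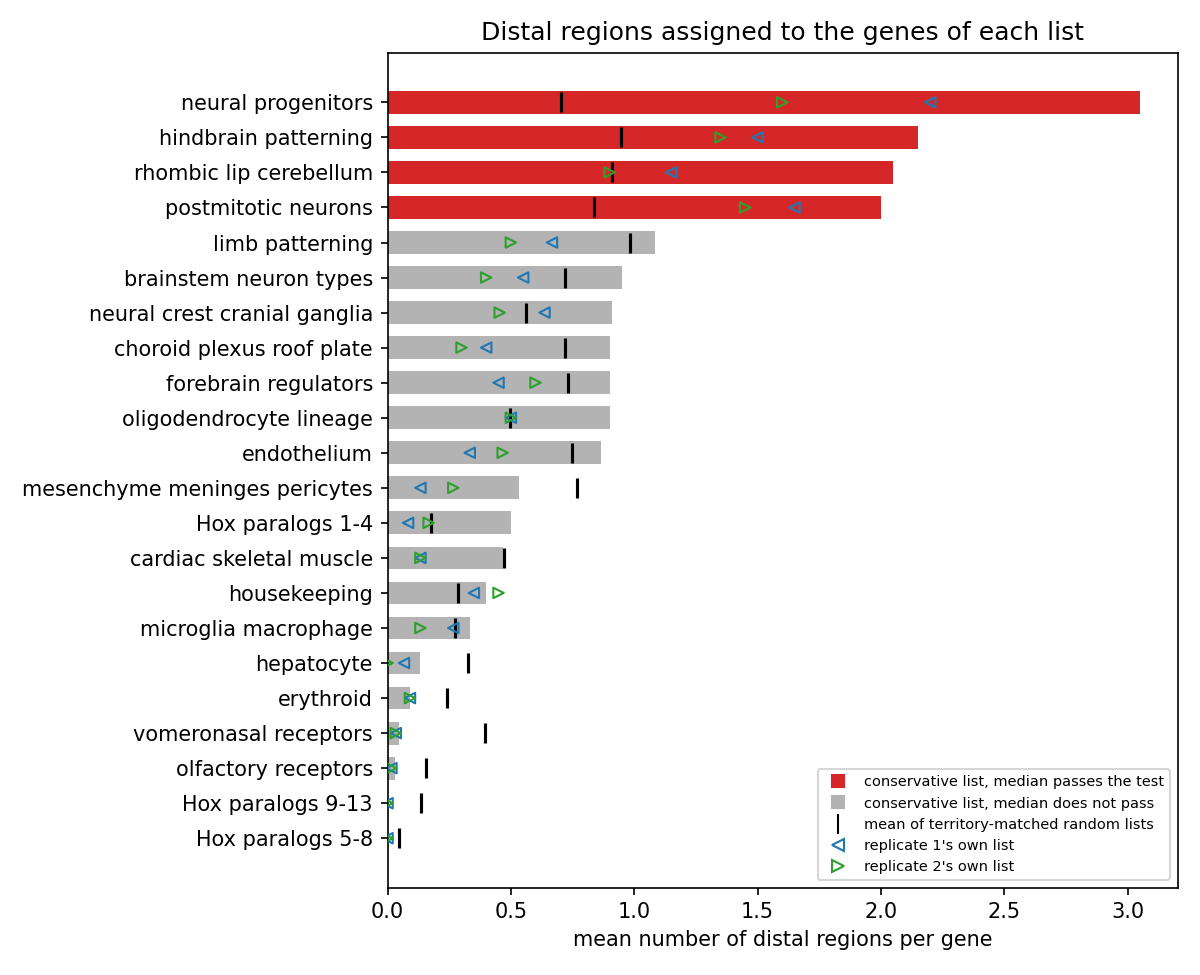
Mean number of distal regions assigned per gene (x axis) in each gene list (y axis), with bars for the conservative list, triangles for each replicate's own list and black ticks for territory-matched random lists. Neural progenitor genes had 3.05 per gene and hindbrain patterning genes 2.15, and red bars mark the 4 lists whose median passed the test.

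The single genes with the most distal regions were ranked by count, with no correction for the length of their territories. Nrxn3, a presynaptic adhesion gene, had 19 in the conservative list, 9 in replicate 1's own list and 10 in replicate 2's, in a territory of 759 kb, and its promoter had a fold of 9.54. Gse1 had 18 and the Notch coactivator Maml3 16, with 11 and 7, and 11 and 10, in the replicates' own lists, and the corepressor Ncor2 and the centrosomal gene Sfi1 13 each. Auts2, in a territory of 825 kb, the chromatin remodeller Chd7, Frmd4a, the neuronal transcription factor Mef2c and Sertad2 had 11 each, and Mef2c also had 11 in replicate 2's own list, more than Nrxn3. Casz1, Gm26897, the microtubule gene Map1b, the adhesion gene Nrcam and Zfp516 had 10 each. Of the 13 regions of Sfi1, 6 had another near-identical copy in the reference, against 0 for each of the other 14 genes.

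The strongest distal regions of all were mostly in repeated or mitochondrial-like sequence. The highest fold was 51.8 ± 0.96 (SD, n = 2) in an intergenic region of chromosome X, 143482935 to 143483180, whose sequence had 6 other copies in the reference. Next came chromosome 2, 69355470 to 69355735, at 40.8 ± 1.55, which held 129 bp with 100% identity to mitochondrial DNA, and chromosome 2, 3964426 to 3964690, at 38.9 ± 3.71, with neither feature. Mitochondrial-like stretches also lay in the regions on chromosome 10, 96077549 to 96077953 (fold 32.1, 349 bp, in the pseudogene AC115970.1), chromosome 5, 60042765 to 60043138 (29.8, 336 bp), chromosome 12, 97061368 to 97061856 (28.5, 365 bp), and chromosome 4, 80002696 to 80003057 (24.0, 361 bp, in the pseudogene Gm11407). The remaining 3 had other copies in the reference. They lay in the processed pseudogene Gm10060 (chromosome 8, 19784427 to 19785254, fold 25.3), an untranslated exon of Lars2 (chromosome 9, 123461727 to 123462252, 23.4) and an intron of Cldn34d (chromosome X, 76598490 to 76599194, 22.9).

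Hox genes, whose anterior paralogs are active in the hindbrain and whose posterior paralogs are active in the trunk, were open mostly in the anterior groups in the conservative list. Neither replicate's own list showed this order past the threshold, but few Hox genes were open in those lists. In the conservative list, of paralog groups 1 to 4, 6 of 12 genes were open, of groups 5 to 8, 0 of 11, and of groups 9 to 13, 1 of 16. The folds were 5.44 ± 1.29 (SD, n = 2) at Hoxa1, 5.15 ± 0.0285 at Hoxd1, 4.43 ± 0.0672 at Hoxa2, 4.39 ± 0.285 at Hoxa4, 4.00 ± 0.24 at Hoxb4 and 3.62 ± 0.186 at Hoxc4. Hoxb1, Hoxb2 and Hoxd4 had no conservative promoter region. The only open posterior gene was Hoxd9, at 4.51 ± 0.0539 (chromosome 2, 74697491 to 74698488), and Hoxa9, Hoxb9, Hoxc9 and the paralogs of group 13 had none. Genes without a conservative promoter region, which were most of the 39, entered the tests at a fold of 0. Across the 39 genes, fold fell with paralog number (Spearman's rho = -0.45, permutation p = 0.00352), a result that rests mostly on open against closed calls. Mean log2 of fold plus 1 was 1.23 in groups 1 to 4 and 0.15 in groups 9 to 13, a difference of 1.07 (permutation p = 0.0199). With each replicate's own list and fold, a test added after the data were seen, rho was -0.14 in replicate 1 (permutation p = 0.538) and -0.17 in replicate 2 (permutation p = 0.296), and the differences were 0.19 (permutation p = 0.428) and 0.45 (permutation p = 0.283). Replicate 1's own list had 1 open gene in groups 1 to 4 and 0 in the other groups, so neither of its tests could have passed. Replicate 2's own list had 3 open genes in groups 1 to 4, 0 in groups 5 to 8 and 1 in groups 9 to 13.

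Neighbouring Hox genes are not independent, and no single cluster passed after adjustment. In Hoxb and Hoxc only Hoxb4 and Hoxc4 were open, so the tests of these clusters could not have passed. In the Hoxa cluster rho was -0.73 (permutation p = 0.0144, adjusted p = 0.0578), in Hoxb -0.17 (adjusted permutation p = 0.801), and in Hoxc -0.55 and Hoxd -0.46 (adjusted permutation p = 0.331 for each). As gene lists, groups 5 to 8 (adjusted p = 0.000205) and 9 to 13 (adjusted p = 0.000125) had fewer open promoters than other genes, and groups 1 to 4 did not differ (adjusted p = 0.603, all by Fisher's exact test). Matching on CpG left both posterior lists lower, at 0% against 88.8% and 6.25% against 85.9% (adjusted permutation p = 0.0011 for each). In the authors' replicated list 12 of 12, 5 of 11 and 5 of 16 promoters were open, the difference of groups 1 to 4 from other genes became 35.6 percentage points (adjusted p = 0.0148, Fisher's exact test), and groups 5 to 8 no longer passed (45.5% against 64.4%, adjusted p = 0.315, Fisher's exact test). Above the median fold groups 1 to 4 fell below other genes (adjusted p = 0.0274, Fisher's exact test). In the replicates' own lists groups 1 to 4 had 1 open gene in replicate 1 (adjusted p = 0.00483, Fisher's exact test) and 3 in replicate 2 (adjusted p = 0.116, Fisher's exact test).

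**Figure D3:**
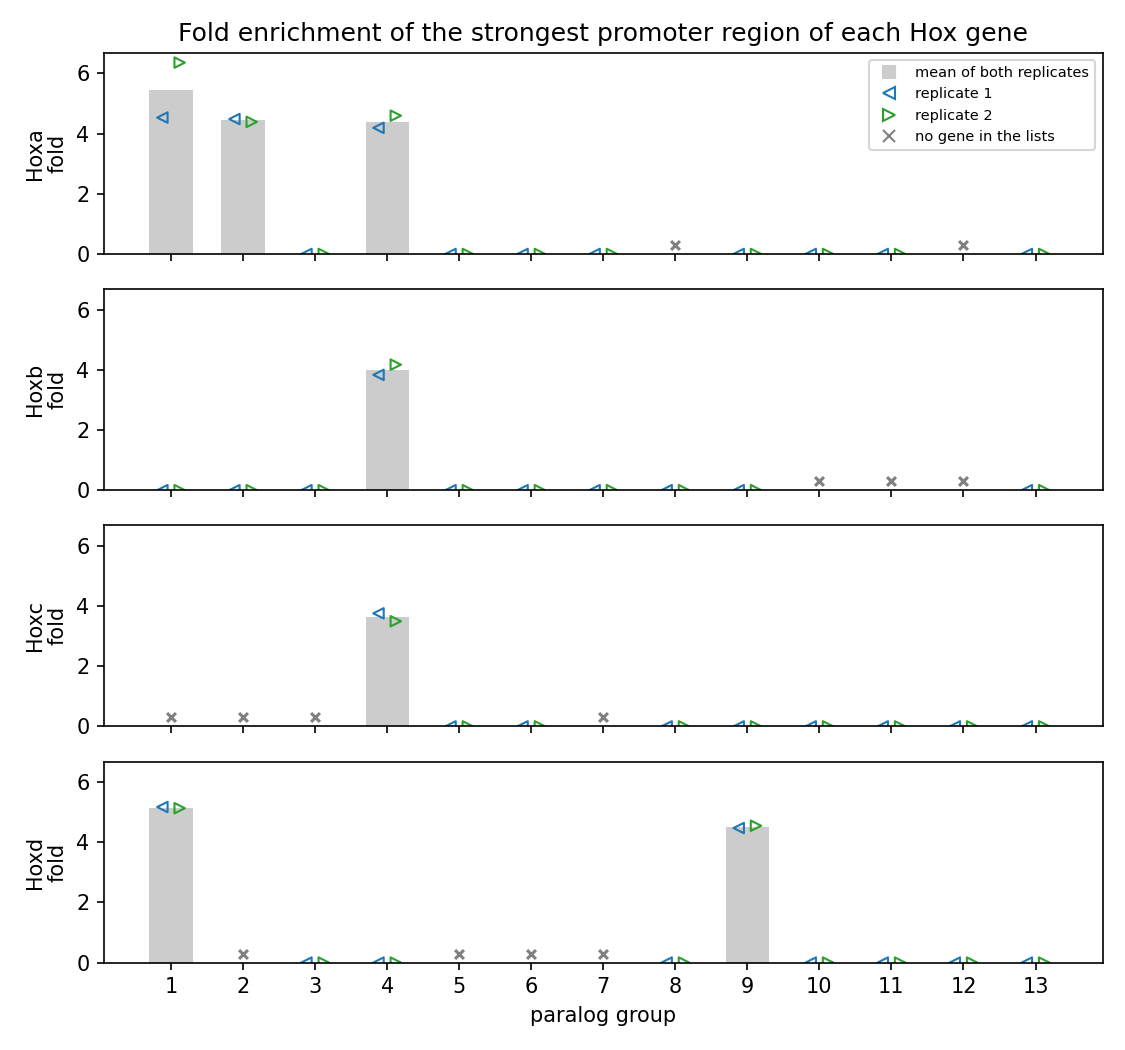
Fold of the strongest region within 1 kb of a TSS (y axis) for each Hox gene by paralog group (x axis), 1 panel per cluster, with bars for the mean and triangles for each of the 2 replicates. Genes without a conservative region are drawn at 0, crosses mark paralogs missing from a cluster, and 6 of the 7 open genes lie in groups 1 to 4.

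Distal regions carried most, though not all, of the motifs listed for neural transcription factors more often at their summits than in flanking sequence. Matches within 100 bp of the summit were compared with windows 400 to 600 bp away, for 24 consensus motifs in promoter and distal regions apart. Flanking windows that overlapped a region or held unknown bases were left out. This left 4128 for 12484 promoter summits and 12714 for 13301 distal summits, so summits were not paired with their own flanks. In distal regions the proneural E-box CAGCTG, bound by bHLH factors such as Ascl1, occurred in 9.25% of summit windows against 2.16% of flanks (adjusted p = 2.28e-141, Fisher's exact test). SOX motifs occurred in 8.20% against 3.89% (adjusted p = 3.84e-48, Fisher's exact test), the octamer of POU factors in 3.84% against 1.41%, and ZIC motifs in 1.20% against 0.181%. RFX motifs, bound by regulators of ciliary and neural genes, were found in 0.526% against 0.00787%, and their shorter single-site form in 4.82% against 1.06%. MEIS motifs were present in 1.68% against 0.582%, PBX/HOX motifs in 1.11% against 0.637%, the homeodomain core TAATTA in 3.13% against 2.09%, the E-box CAGATG in 3.16% against 1.86%, EBF motifs in 1.08% against 0.425% and full NFI palindromes in 0.135% against 0%. TAATCCC, bound by OTX-type homeodomains and also listed as neural, was depleted (1.54% against 3.12%, adjusted p = 4.95e-17, Fisher's exact test). CTCF, the insulator protein, had its core motif in 4.70% against 0.142% (adjusted p = 3.27e-155, Fisher's exact test). In single-replicate lists TAATTA no longer passed without replicate 2 (adjusted p = 0.0679, Fisher's exact test), nor PBX/HOX without replicate 1 (adjusted p = 0.107, Fisher's exact test). With 50 bp on each side of the summit, NRF1 at distal regions (adjusted p = 0.0569) and ZIC and HNF4 at promoters (adjusted p = 0.186 and 0.0674, all by Fisher's exact test) lost their calls.

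None of the motifs chosen for other tissues was enriched at distal summits over the flanks. The GATA motif of blood cells was depleted (0.767% against 1.59%, adjusted p = 1.49e-09, Fisher's exact test). SPI1, HNF1, HNF4, MEF2, AP-1 and TEAD motifs did not pass the test against the flanks. Against permuted motifs SPI1 (log2 odds 0.91, adjusted p = 0.000418), HNF4 (1.15, adjusted p = 0.000437) and TEAD (0.81, adjusted p = 6.87e-26, all by Fisher's exact test) passed, a test that pools the 20 permuted forms of each motif. The most frequent permuted form was more frequent than the motif itself for HNF4 (0.218% against 0.203%) and TEAD (5.32% against 3.50%). It was less frequent for SPI1 (0.248% against 0.316%). Among motifs enriched over the flanks at distal summits, the most frequent permuted form also exceeded EBF (2.68% against 1.08%), CAGATG (3.40% against 3.16%), TAATTA (3.19% against 3.13%) and ETS (1.62% against 0.594%). In all, 16 of 24 motifs were enriched and 2 depleted at distal summits. Promoter summits carried NFY motifs in 15.4% against 1.19% (adjusted p = 6.41e-183, Fisher's exact test), ETS in 6.99% against 0.291%, NRF1 in 1.48% against 0%, CAGCTG in 4.28% against 1.82% and CTCF in 0.857% against 0.194%. These 5 were enriched at distal summits too, where NFY stood at 4.89% against 1.88%, ETS at 0.594% against 0.173% and NRF1 at 0.143% against 0.0236%, and the difference between the region classes was not tested. At promoters 8 motifs were enriched and 8 depleted. The enriched ones included SPI1, a motif chosen for myeloid cells (0.569% against 0.121%, adjusted p = 7.97e-05, Fisher's exact test). Summit windows were richer in G and C than flanks, 66.0% against 45.1% at promoters and 53.7% against 43.4% at distal regions. With permuted motifs as the background the promoter depletion of HNF4, MEF2, TEAD and PBX/HOX motifs turned into log2 odds of 1.23, 0.93, 0.36 and 0.21, the last of which did not pass (adjusted p = 0.523, Fisher's exact test).

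**Figure D4:**
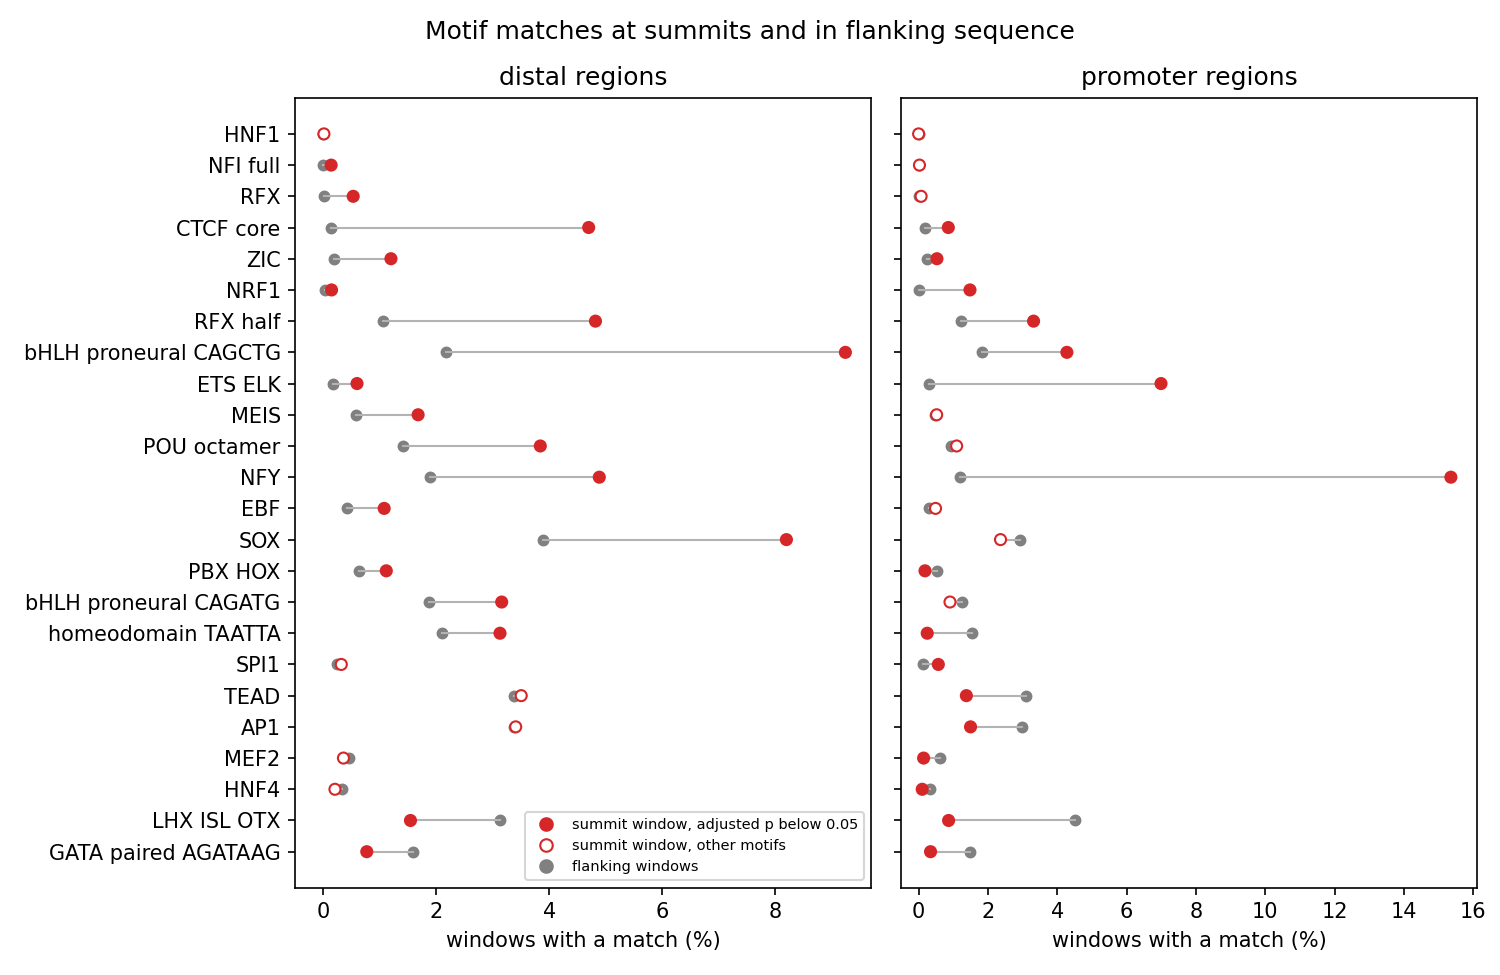
Share of windows with a motif match (x axis, percent) at summits (red) and in flanking sequence (grey) for 24 consensus motifs (y axis) in distal and promoter regions, where filled red points passed the test and open ones did not. The proneural E-box CAGCTG reaches 9.25% at distal summits against 2.16% in flanks, and NFY reaches 15.4% at promoter summits against 1.19%.

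The conservative list and the authors' optimal list, which held 26312 regions, were largely alike. Of the conservative regions, 23154 (89.8%) overlapped an optimal region, and these made up 88.0% of the optimal list.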

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

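All tests in this part other than the matching on CpG were chosen after the lists had been seen, and those of the number of genes and of signal on chromosome X after the values they measure.

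The authors' ranked table held 145 regions past the IDR threshold that do not stand in the conservative list, data that no comparison used, except that those on chromosomes entered the values over all ranked regions. Of these, 65 lay on unplaced scaffolds and 80 on chromosomes, with a median fold of 4.45. The highest fold was 48.6, at chromosome 9, 24541943 to 24542232, close to the maximum of 53.8 in the conservative list.

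Among the 10 strongest distal regions that were kept, 5 held a stretch similar to mitochondrial DNA, against 0 of 200 random distal regions (p = 7.77e-08, Fisher's exact test), and 7 had another copy in the reference, against 3 of 200 (p = 4.29e-09, Fisher's exact test). For these 5, nuclear copies of mitochondrial DNA that take up mitochondrial reads are a candidate source, with mean fold values from 24.0 to 40.8, and 3 of the 5 had another nuclear copy as well. The 7 with copies fell short of the 8 set in advance as needed for repeated sequence to account for the whole group, so that explanation stays open. The region at chromosome 2, 3964426 to 3964690, had neither feature. The single group of the design offers no contrast, so no biological explanation was tested.

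Chromosome X held 4.21 regions per Mb, against a median of 10.2 and a lowest value of 7.92 over the autosomes, and 1.51 distal regions per Mb against 5.47. Fewer genes do not account for the whole deficit, with 0.726 regions per coding gene on X and at least 0.841 on each autosome, nor does repeat-masked sequence, with 7.90 regions per unmasked Mb and at least 12.1 on each autosome. A lower signal from fewer open copies was taken to predict lower promoter folds. The upper quartile of promoter fold over genes of above-median CpG was 1.02 times the autosomes' median. Fold is a ratio to the local background, which may itself fall with the number of copies, so this cannot exclude fewer copies. Median distal fold on X was 5.40 in replicate 1 and 5.41 in replicate 2, above the highest autosome at 5.33 and 5.30. Promoters of such genes were open in 92.8% of cases on X and 92.3% on the median autosome, and the deficit was larger for distal regions (0.276 of the autosomes' median per Mb) than for all regions (0.413). What accounts for it remains open, and beyond the number of open copies no biological explanation was tested.

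The CpG content of promoters may account for part of the gene list results. Among random lists matched on CpG, the share of open promoters stood at percentile 50.3 for hindbrain patterning, 53.4 for progenitors, 13.2 for microglia and 12.6 for hepatocytes. In the conservative list the progenitor genes stayed within the range set in advance for CpG content to account for them. With 20 of 20 open they would have passed (adjusted permutation p = 0.0236). All 20 were open in the optimal list, the replicated list and replicate 1's own list, and 16 in replicate 2's. CpG matching was not run on those lists, so the progenitor result is not settled. The other 3 stay open, since even all or none of their promoters open would have given an adjusted permutation p of 0.0717, 0.0845 and 0.161. In the conservative list CpG content was not enough for the neuron list, at percentile 99.6, nor for the muscle list, at 0.025. For these too, matching was not run on the other lists, where the open counts differed. Neuron genes had 15 and 16 of 20 open in the replicates' own lists and 20 in the replicated list. Muscle genes had 0 of 15 open in either replicate's own list and 5 in the replicated list. CpG content is itself a property of gene classes, a match on it does not separate sequence from regulation, and no biological explanation was tested.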

How the results depend on the processing

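The top 10000 regions, the rule of any overlapping peak, the Hox tests on the replicated list and on each replicate's own list and the count of replicate-biased regions over all ranked regions were added after the data were seen, and all other alternatives were planned. The planned comparison of the 20000 strongest regions was not run, since each replicate's list is shorter. Of 106 main values under alternatives, 64 stayed within their spread or on their side of the threshold and 42 did not.

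Replicate overlap was 83.1% at 50% reciprocal overlap, 74.5% for summits within 100 bp, 78.4% in the overlap lists, 89.6% for unmerged peaks and 87.9% for the top 10000 regions. The correlation was 0.952 with −log10 p, 0.912 over all ranked regions with a value in each replicate and 0.862 above the median fold. Unmerged, the conservative list held 76635 peaks, at an IDR of 0.01 it held 19838 regions, a fall within the 1.5-fold bound for counts, and the overlap lists held 46813.5 regions per replicate. The promoter share was 47.2% at 0.5 kb, 50.5% at 2.5 kb, 47.4% in the optimal list, 26.2% in the replicated list and 59.2% to 59.4% with 1 replicate left out. The promoter excess over distal regions was 0.61 at 2.5 kb and 1.66 with −log10 p, on the log2 scale. Replicate-biased regions were 1.21% at 1.5-fold and 1.92% with −log10 p. They were 0.184% (65 regions) of the 35385 among 62207 ranked regions that had a value in each replicate. Ranked regions that lacked a value in a replicate were left out, so this set too was selected for agreement. With any overlapping peak the share was 0.0437% (11 regions), where peaks with a summit outside the region made the difference.

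Lists with more open promoters numbered 7 in the replicated list, 1 above the median fold, 1 with CpG matching and 2 to 3 with a replicate left out (2 without replicate 2), and lists with fewer were 12 above the median fold. Among lists past the threshold in either setting, directions turned above the median fold for hindbrain patterning (-9.53 percentage points), rhombic lip (-29.5) and progenitors (-19.5), where weaker regions are left out by construction, and in the replicated list for brainstem types (25.6) and Hox groups 1 to 4 (35.6), where more regions are admitted. A further 9 differences turned without passing in either setting: in the replicated list for choroid plexus (15.6), forebrain (10.6), mesenchyme (2.26) and limb genes (10.6), with CpG matching for rhombic lip (-14.5), neural crest (-18.0) and erythroid genes (13.5), at 2.5 kb for forebrain genes (0.878) and in the optimal list for Hox groups 1 to 4 (0.561). Lists with more distal regions numbered 2 at 50 kb (without hindbrain patterning and rhombic lip), 3 in the optimal list (without rhombic lip), 1 above the median fold and 1 with either replicate left out, and 2 had fewer by the mean. Distal differences turned in 20 cases without passing in either setting and in 15 with a value within 0.01 of 0. With permuted motifs 15 promoter motifs were enriched and 4 depleted, and log2 odds turned for SOX (0.48), PBX/HOX (0.21), EBF (-1.38), HNF4 (1.23), MEF2 (0.93) and TEAD (0.36) at promoters and HNF4 (1.15) at distal regions, and 9 other log2 odds turned without passing in either setting. The cause was not tested in the cases where none is named. The Hox paralog gradient passed in the conservative list at 2.5 kb and by covered bp within 5 kb, and in the replicated list. It did not with each replicate's own list and fold, where rho was -0.14 in replicate 1 and -0.17 in replicate 2 (permutation p = 0.538 and 0.296) and the difference of means 0.19 and 0.45 (permutation p = 0.428 and 0.283). Replicate 1's tests could not have passed, with only 1 Hox gene open in its own list. The folds of either replicate at the conservative regions share their open calls, so they are no separate check. Hox groups 5 to 8 lost their call as a gene list in the replicated list (adjusted p = 0.315, Fisher's exact test). Of 791 open or closed calls of named genes under alternatives, 74 changed, 28 of them in the replicated list. Hoxb1 and Hoxb2, closed in the conservative list, were open in the replicated list, which has a looser rule. The limit set by depth was not assessed, since no read totals were used.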

Other observations

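All gene families below were chosen and tested after the data had been seen, 25 in all, by Fisher's exact test and by random lists matched on CpG or territory, with adjustment over the families. Where the adjusted p is 0.000833, the raw p was 0.0002, the smallest that 10000 permutation lists can give.

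Several families of transcription factors had more distal regions than territory-matched lists, and families were not tested against each other. Of the 25 families, 9 passed on distal regions, 6 with more and 3 with fewer. Nuclear factor I genes, regulators of glial and neuronal maturation, had a mean of 4.5 distal regions per gene against 0.945 in territory-matched lists, Pax genes 3.11 against 0.989, POU genes 2.13 against 0.833 and Sox genes 1.95 against 0.824 (adjusted permutation p = 0.0279 for each). Forkhead (adjusted permutation p = 0.0705), LIM homeodomain (0.163), paired-like and Dlx (0.461) and T-box genes (0.634) did not pass. In replicate 1's and replicate 2's own lists, which were not tested, the means were lower, 3.5 and 3 for nuclear factor I, 1.89 and 2 for Pax, 1.33 and 1.4 for POU and 1.37 and 1.26 for Sox genes. Histone cluster 1 genes had 0.259 against 0.0571 (adjusted permutation p = 0.005), and cytochrome P450 genes (0.22 against 0.457, adjusted permutation p = 0.0279) and beta-defensins (0.0238 against 0.2, adjusted permutation p = 0.0461) had fewer. The means in the replicates' own lists were 0.148 and 0.167 for histone genes, 0.12 and 0.12 for cytochrome P450 genes and 0.0476 and 0 for beta-defensins. Wnt ligands had 1.37 distal regions per gene against 0.559 (adjusted permutation p = 0.0306), and 0.895 and 0.842 in the replicates' own lists. Only 7 of 19 Wnt promoters were open, 36.8% against 76.8% in CpG-matched lists (adjusted permutation p = 0.000833), and 2 in each replicate's own list. Forkhead genes (52.3% against 80.1%) and paired-like and Dlx homeobox genes (62.9% against 88.7%) also had fewer open promoters than CpG-matched genes (adjusted permutation p = 0.000833 for both). Against all other genes, of which 57.8% to 57.9% were open, none of these 3 passed (adjusted p = 0.158 for Wnt, 0.536 for forkhead and 0.693 for paired-like and Dlx genes, Fisher's exact test). The large family of Zfp zinc finger genes had more open promoters than CpG-matched genes, with 334 of 394 promoters open (84.8% against 68.2%, adjusted permutation p = 0.000833).

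Families of cell surface proteins, receptors, channels and keratins were set against CpG-matched genes in the same way. None of the 51 clustered protocadherin promoters, a family expressed in differing combinations by single neurons, was open, against 57.3% of CpG-matched genes (adjusted permutation p = 0.000833). Non-clustered protocadherins (83.3% against 77.4%), ephrins and Eph receptors (86.4% against 87.1%), glutamate receptor subunits (75% against 71.9%) and potassium channels (73.3% against 76.0%) did not pass (adjusted permutation p = 1 for each), although ephrins and Eph receptors were open more often than all other genes (adjusted p = 0.0181, Fisher's exact test). Semaphorins of classes 3 to 7, which guide axons, were open in 19 of 20 cases (95% against 77.9%, adjusted permutation p = 0.0393). GABA-A receptor subunits were open in 11 of 12 (91.7% against 65.6%, adjusted permutation p = 0.0481), yet had 0.0833 distal regions per gene against 0.977 (adjusted permutation p = 0.0279). Of 53 keratin promoters none was open, against 27% of CpG-matched genes (adjusted permutation p = 0.000833). In replicate 1's and replicate 2's own lists the open promoters numbered 11 and 11 for GABA-A subunits, 16 and 15 for semaphorins and 0 in both for protocadherin clusters and keratins.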
